A study of Arabidopsis thaliana with 8 samples.

How the data were processed

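Nascent RNA was measured by nuclear run-on with a bromo-UTP label and enrichment of the labelled RNA with an antibody to BrdU, per the labels' protocols. The 8 libraries formed 4 groups of 2, taken from the titles of the samples: untreated seedlings (Wt), heated seedlings (Heat), mock-infiltrated leaves (Mock) and leaves infiltrated with Pseudomonas syringae DC3000 (DC3000). Each deposited file lists 335459 features with 1 FPKM value each, per the file headers, which name HOMER. Bowtie2 2.3.5, HOMER 4.11.1 and edgeR 3.26.5 are named in the submitters' processing notes, without their order or settings. The FPKM values as deposited are scaled to all tags of a library and to feature length. Coordinates are those of the files, on TAIR10, counted from 1. All 335459 features are listed on the plus strand, so sense and antisense reads could not be told apart, and 3973 of 28440 nuclear gene loci overlap another gene locus. Names and biotypes came from a reference table on TAIR10.1, used for nothing else, which matched 27982 gene loci and gave a symbol for 10594.

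The planned test assumed counts. The files held FPKM, so the test fixed for that case was used. What 1 read is worth at each feature's length was estimated from the values. In each library 100% of the values checked, those worth fewer than 100 reads, were whole multiples of it within 0.1 reads. Larger values were rounded to whole reads without this check. These steps gave the reads per feature and the library totals. Ribosomal DNA (103 features, with a margin of 6000 bp), organelle features (279, with 0 reads in all libraries), the non-coding RNA catalogue (9164 features) and intergenic segments of at most 200 bp were kept apart from gene loci. FPKM were rescaled to the reads in nuclear gene loci, since the ribosomal share differed between groups. Reads in gene loci ranged from 1475940 (Wt replicate 2) to 6961949 (DC3000 replicate 1).

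A gene was tested if its value was above 1 in at least 2 libraries (22528 loci). Values were transformed to log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 fitted 4 group means over all 8 libraries without covariates. Its empirical Bayes step used a trend and the robust option, with 4 residual degrees of freedom before moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Adjusted p-values of genes in the report are from limma, and those of lists are from camera with a preset correlation of 0.01, repeated with an estimated correlation and adjusted over lists. The comparisons were Heat minus Wt, DC3000 minus Mock, Mock minus Wt as context, and the difference of the first pair. Fisher's exact test of overlaps against independent lists was planned, since the responses share no library, but is not used here: both responses take their residual variance from the same fit, so their calls are not independent. For a group with 0 reads a bound was computed against a floor of 3 reads over the group, and with 1 to 3 reads an exact 95% interval of the read ratio was given. Intervals and bounds cover counting error only.

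Before the data were examined, 17 lists with 343 genes were fixed, of which 342 were measured and HSFB1 was not analysed here. HSP70-18, HSFA6A, HSFA7B, JAZ4, AHG1, SAG12, PLT1, PLT2 and SMB were measured but too low to test. Lists by gene description were not tested, since no descriptions were used here. Genes were named by a rule fixed at the same time: a set always named, the 6 largest called rises and falls with a symbol, a mean of at least 2 CPM and no overlap of groups (4 each way for leaf against seedling, 5 for the difference), and up to 4 members per list. From lists with fewer than 2 called members, the 2 with the highest mean were taken. Other genes named were chosen after their values were seen.

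The procedure was tested on simulated data with known changes in 200 genes, 50 per size. Apart from these changes all groups had the same mean per gene. Libraries were drawn independently, with the same dispersion for all genes of a group. In the real data the deviations of same-numbered Wt and Heat libraries correlated at 0.607, so the simulated rates may not hold for the real calls. The simulated rates also came from 200 changed genes, against 3235 loci called for DC3000, and the adjusted p depends on that number. Of 2-fold, 4-fold, 0.5-fold and 0.25-fold changes, it recovered 12%, 88%, 18% and 48% for the heat comparison and 10%, 88%, 10% and 66% for DC3000. False calls lay mostly below 2 CPM.

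Alternatives fixed beforehand were the pseudocount (0.1 and 5), the filter, the groups in the fit, the replicate number as a block, an estimated correlation and leaving out each library. Count-model tools were planned but not run, since the deposited values are FPKM, although reads were recovered from them. In their place, and chosen after seeing the data, stood voom on the recovered reads (with and without the block), median-of-ratios and deposited scaling, a 1.5-fold threshold and empirical Bayes without the robust option. Fits were looked at in an exploratory pass before the final ones. Clock phases were assigned after the replicate difference of LHY was seen, and the analyses of the non-coding catalogue, of flanking reads and of intergenic distance were also chosen after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.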

Results

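Nascent transcription was measured by global run-on sequencing (GRO-seq) in Arabidopsis thaliana of the Columbia background. In this assay nuclei extend the RNA that engaged polymerases already carry, with a labelled nucleotide, and the labelled RNA is sequenced, so the signal of a locus reflects polymerase on it and not stored RNA. The 8 libraries formed 4 groups of 2. Whole 12-day-old seedlings were left untreated (Wt) or held at 37 °C for 0.5 h (Heat). Leaves of plants kept on soil to an age of 24 days were infiltrated with 10 mM MgSO4 (Mock) or with Pseudomonas syringae pv. tomato DC3000, a bacterial leaf pathogen, at an OD600 of 0.001 (DC3000), and collected 24 h later. Nothing in the labels says that replicates were separate plants or cultures, so p-values measure the spread between these samples. The fit pooled that spread over all 4 groups, although it differed between them. Among loci averaging 10 CPM or more, replicates differed over 2-fold at 10.0% in Wt, 4.0% in Heat and 2.4% in Mock and in DC3000. The p-values of each comparison thus depend on groups outside it. Values are FPKM (reads scaled by locus length and library size) rescaled to the reads in nuclear gene loci, given as mean ± SD with n = 2.

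The libraries held between 5.74 M tags (Wt replicate 2) and 14.3 M tags (DC3000 replicate 1). Reads in the 28440 nuclear gene loci numbered 2997898 and 1475940 in Wt, 1940450 and 2201514 in Heat, 2857630 and 2497694 in Mock, and 6961949 and 3922543 in DC3000. Of these loci, 22528 were tested. Ribosomal DNA took 23.3% ± 3.65 of tags in Wt, 24.2% ± 0.332 in Heat, 23.49% ± 1.62 in Mock and 8.78% ± 3.21 in DC3000. Intergenic segments took 4.73% ± 1.27, 4.45% ± 0.489, 4.61% ± 0.616 and 10.7% ± 0.429 of tags in the same order. Groups of 2 cannot pass an exact permutation test, whose smallest two-sided p is 0.333, so these shares are given without one.

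**Figure D1:**
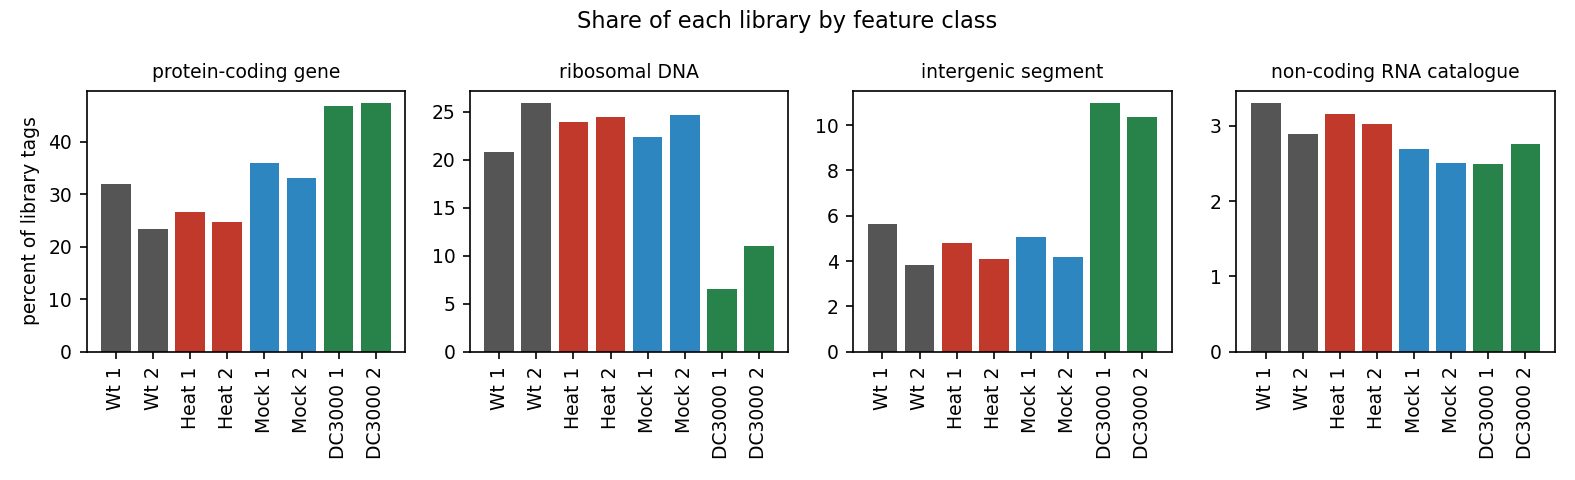
Bars give the percentage of each library's tags in protein-coding genes, ribosomal DNA, intergenic segments and the non-coding RNA catalogue, 1 bar per library, coloured by group. The DC3000 libraries held 6.51% and 11.05% ribosomal DNA, against 20.8% or more in the other 6 libraries, and over 10% intergenic tags.

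The first comparison asked which loci changed their transcription in seedlings after 0.5 h at 37 °C. Among the loci that rose were genes of chaperones and of a heat shock factor. HSP90.1, a cytosolic HSP90 chaperone (AT5G52640, chromosome 5 from 21352399 to 21355361 in TAIR10), rose from 8.98 ± 2.18 to 296 ± 64.1 FPKM. HSFA2, a heat shock transcription factor (AT2G26150, chromosome 2 from 11135682 to 11137396), rose from 2.36 ± 1.14 to 95.4 ± 11.3 FPKM. HSP101, the disaggregating ClpB chaperone of the cytosol (AT1G74310, chromosome 1 from 27936508 to 27940190), rose from 8.06 ± 2.82 to 164 ± 2.67 FPKM. In all, 32 loci rose and 12 fell, and 21 of the 32 belonged to the lists of small heat shock proteins, large chaperones, heat shock factors or other heat-response genes.

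Small heat shock proteins, which hold unfolding proteins in a refoldable state, had 7 of 16 tested members that rose, 0 that fell and 9 that were not called, or 14 that rose when adjusted over the list alone. Their median log2 change was 4.54, and 15 of 16 were positive. HSP17.8 (AT1G07400, chromosome 1 from 2274943 to 2275758) rose from 6.18 ± 0.516 to 302 ± 68.6 FPKM, a log2 change of 5.38 ± 0.32 (SE) with a limma adjusted p of 0.00293. HSP17.6B rose from 3.53 ± 0.372 to 146 ± 80.7 FPKM (log2 change 4.90, adjusted p = 0.0113). HSP17.6II had 1 read in the Wt group and 289 in the Heat group, a read ratio of 312 with a 95% exact interval of 55.6 to 12372. HSP23.6 had 1 and 164 reads, a ratio of 177 (31.4 to 7039). HSP21, not called, had 0 Wt and 29 Heat reads, at least 10.4-fold higher against a floor of 3 reads over the group, and the list median stayed at 4.54 with HSP21 at that bound. These intervals and bounds cover counting error only. The set test camera gave the list an adjusted p of 1.16e-32, and an adjusted p = 0.0969 with an estimated correlation.

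Among 28 tested large chaperones and co-chaperones, 11 rose, 0 fell and 17 were not called, and 19 rose when adjusted over the list alone. ROF2, a peptidyl-prolyl isomerase of the FKBP family, rose from 2.71 ± 2.26 to 108 ± 35.3 FPKM (log2 change 4.99, adjusted p = 0.0107). HSP70-4 rose from 19.9 ± 13.5 to 542 ± 140 FPKM (log2 change 4.84, adjusted p = 0.02). HSP70 and HSP90 genes have near-identical copies, and how the deposited values divide reads between them is not stated, so their individual levels are uncertain. The list median was 1.38, the adjusted p 5.44e-40, and the adjusted p = 0.0041 with an estimated correlation, the only one of the 7 lists called after heat that held there.

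HSFA2 was the 1 heat shock factor of 18 tested that rose, with 17 not called and 3 rising when adjusted over the list alone. HSFA9 stood at 298 ± 120 and 348 ± 6.48 FPKM and HSFA4A at 34.3 ± 10.8 and 31.6 ± 6.79, neither called. HSFA9 overlaps the U3D small nucleolar RNA locus over 18% of its length, so reads of the latter may be counted in it. The list had a median of 0.44 and an adjusted p of 8.61e-06, and an adjusted p = 0.227 with an estimated correlation. Of 12 other heat-response genes, 2 rose and 10 were not called, with 4 rising when adjusted over the list alone. MBF1C, a transcriptional coactivator, rose from 23.56 ± 7.55 to 241 ± 5.39 FPKM (log2 change 3.33, adjusted p = 0.00856), although 12.3% of its length overlaps ALDH2C4. HSA32, a chaperone of acquired thermotolerance, rose from 3.77 ± 0.355 to 21.5 ± 0.564 FPKM (log2 change 2.24, adjusted p = 0.0267). APX2, a cytosolic ascorbate peroxidase, stood at 3.17 ± 1.39 and 2.02 ± 0.495 FPKM (adjusted p = 0.957). The list's median was 0.39, with an adjusted p of 0.000149, and an adjusted p = 0.216 with an estimated correlation.

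ERDJ3A, an endoplasmic reticulum J protein, rose from 1.80 ± 0.298 to 11.3 ± 0.364 FPKM and was the 1 of 13 unfolded protein response genes that rose (list median 0.09, adjusted p = 0.0695), with 1 rising when adjusted over the list alone and 0 called with the scaling as deposited. BZIP60 stood at 103 ± 46.4 and 108 ± 32.7 FPKM and HSP90.7 at 37.1 ± 3.69 and 40.2 ± 2.37. No member was called in the other 12 lists, where limma left 0 calls. Abscisic acid genes had a median of 0.33 and a list adjusted p of 0.00324 (1 rose when adjusted over the list alone), auxin response genes 0.34 and 0.0163, and epidermis markers −0.23 and 0.0481. With an estimated correlation the adjusted p was 0.251, 0.729 and 0.448 for these 3 lists. PP2CA stood at 91.8 ± 31.4 and 124 ± 16.4 FPKM, CYP707A3 at 94.8 ± 12.1 and 97.6 ± 48.1, IAA2 at 179 ± 51.9 and 219 ± 82.4, PIF4 at 29.4 ± 29 and 53.9 ± 27.3, TGG1 at 296 ± 47.3 and 264 ± 19.9, and FDH at 127 ± 29.8 and 89.5 ± 21.4. Medians and list adjusted p were 0.20 and 0.12 for photosynthesis, 0.08 and 0.481 for salicylic acid, −0.09 and 0.592 for pattern-triggered immunity, and 0.01 and 0.592 for jasmonate. They were 0.19 and 0.343 for the circadian clock, 0.11 and 0.289 for senescence, −0.29 and 0.0512 for root markers, −0.07 and 0.776 for phloem and 0.03 and 0.592 for dividing cells, whose mean (−0.11) and test pointed down. Adjusted over the list alone, 1 root marker fell. The salicylic acid, jasmonate and dividing-cell medians changed sign with the scaling, all within 0.1 of 0. The camera adjusted p of root markers was 0.0323 with median-of-ratios factors and 0.0187 with the scaling as deposited. That of photosynthesis was 0.0276 with the scaling as deposited. Lists called after heat numbered 8 with median-of-ratios factors and 9 with the scaling as deposited. WRKY33 stood at 183 ± 60.9 and 157 ± 46.6 FPKM, PEN3 at 142 ± 21.6 and 115 ± 5.46, DMR6 at 25.8 ± 0.135 and 43.9 ± 7.002 and JAZ9 at 65.9 ± 25.8 and 56.5 ± 25.6. The light-harvesting gene LHCB1.1 stood at 2178 ± 861 and 2476 ± 103 FPKM, the Rubisco activase gene RCA at 2461 ± 497 and 2296 ± 33.4, and RBCS1A at 5331 ± 1397 and 5074 ± 395. LHY, a morning clock gene, spread widely, at 133 ± 151 and 79.8 ± 98.8 FPKM.

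Of the 32 rises, 29 lay at loci averaging 2 CPM (recovered reads scaled to gene-locus reads) or more, as did 1 of the 12 falls, and the unadjusted p was under 0.05 at 1263 loci. In simulated data for this comparison, with independent libraries and the same dispersion for all genes of a group, 30 of 113 calls were false. Of the false calls 28 lay below 2 CPM, and 12% of 2-fold and 88% of 4-fold rises were recovered. Fitted on the 4 seedling libraries alone, limma called 0 loci (788 at an unadjusted p under 0.05), and voom on the recovered reads of all 8 libraries called 33 rises, 25 of them shared, and 0 falls. The rises numbered 13 without Wt replicate 2, 7 without Heat replicate 1, 5 without Heat replicate 2, 19 without either Mock replicate, and 13 without either DC3000 replicate. The falls numbered 2 without Heat replicate 2, 7 without Mock replicate 1, 6 without Mock replicate 2, 6 without DC3000 replicate 1 and 7 without DC3000 replicate 2. HSP17.8 and HSP90.1 kept their calls in all 8 of these fits, HSFA2 in 7, HSP101, MBF1C and ROF2 in 6, HSP17.6B in 5, HSP70-4 in 4, HSP17.6II in 3, HSP23.6 in 1 and HSA32 in 0. Of these 11 genes, 2 stayed called without Heat replicate 2, 6 without Heat replicate 1, and 7 without either Wt or either DC3000 replicate. The 7 lists called after heat became 11 without Wt replicate 2.

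The second comparison asked which loci changed in leaves 24 h after infiltration with DC3000, against mock-infiltrated leaves. Of the salicylic acid and jasmonate lists 20 of 32 and 22 of 37 genes rose, and 28 of 48 nuclear photosynthesis genes fell, while each of these lists had an adjusted p = 0.306 with an estimated correlation. ICS1, which makes the precursor of salicylic acid (AT1G74710, chromosome 1 from 28070295 to 28074148), rose from 9.33 ± 1.64 to 106 ± 1.87 FPKM, a log2 change of 3.38 ± 0.21 (SE) with an adjusted p of 0.00157. JAZ10, a repressor of jasmonate signalling (AT5G13220, chromosome 5 from 4218888 to 4220883), rose from 79.8 ± 19.9 to 789 ± 129 FPKM (adjusted p = 0.00451). FLS2, the receptor for bacterial flagellin (AT5G46330, chromosome 5 from 18791736 to 18795546), fell from 69.1 ± 3.55 to 19.5 ± 12.9 FPKM (log2 change −1.93, adjusted p = 0.0392). In all, 2081 loci rose and 1154 fell.

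Of 32 salicylic acid genes, 20 rose, 0 fell and 12 were not called, with 23 rising when adjusted over the list alone and a median of 1.65. WRKY38 rose from 0.804 ± 1.14 to 48.3 ± 1.70 FPKM, PBS3 from 12.3 ± 6.69 to 176 ± 6.35, and NUDT6 from 1.00 ± 0.958 to 14.8 ± 1.296. CBP60G, a transcription factor of the pathway, rose from 84.6 ± 30.5 to 191 ± 44.1 FPKM (adjusted p = 0.0453), and FMO1, of systemic resistance, from 0.766 ± 0.694 to 7.73 ± 2.45 (adjusted p = 0.0104). PR1, a salicylic acid marker, stood at 42.0 ± 39.8 and 40.5 ± 0.235 FPKM and was not called (log2 change 0.35, adjusted p = 0.756). The list had an adjusted p of 6.18e-11, and an adjusted p = 0.306 with an estimated correlation. These DC3000 libraries also held a lower ribosomal DNA share, 8.78% against 23.49% in Mock, and a higher intergenic share, 10.7% against 4.61%, and this holds beside each gene group of this comparison.

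Of 37 jasmonate genes, 22 rose, 0 fell and 15 were not called, with 27 rising when adjusted over the list alone and a median of 1.63. BSMT1, which methylates salicylic acid, rose from 8.53 ± 0.842 to 323 ± 143 FPKM (log2 change 5.02, adjusted p = 0.00157). CLH1 rose from 35.1 ± 2.96 to 524 ± 184 FPKM, VSP1 from 20.2 ± 15.66 to 238 ± 96.2, and TAT3 from 56.8 ± 43.1 to 538 ± 34.7. LOX2, a chloroplast lipoxygenase, stood at 286 ± 24.8 and 1242 ± 117 FPKM and was not called (log2 change 2.12, adjusted p = 0.142), though the call was made with the scaling as deposited and in the fit of the leaf libraries alone. The list had an adjusted p of 8.84e-13, and an adjusted p = 0.306 with an estimated correlation.

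Nuclear photosynthesis genes had 28 of 48 members that fell, 0 that rose and 20 that were not called, with 46 falling when adjusted over the list alone and a median of −1.61. RBCS1B fell from 199.4 ± 73.6 to 29.1 ± 1.95 FPKM, RBCS2B from 633 ± 310 to 124 ± 10.4, and RBCS3B from 1809.8 ± 223 to 360 ± 0.915. LHCB1.4 fell from 1026 ± 442 to 152 ± 9.34 FPKM (log2 change −2.67, adjusted p = 0.0134), and LHCB1.1 from 1476 ± 6.80 to 640 ± 114 (log2 change −1.22, adjusted p = 0.0385). RBCS and LHCB1 genes are near-identical copies, so the share of each is uncertain. The list had an adjusted p of 1.9e-25, and an adjusted p = 0.306 with an estimated correlation.

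Among 9 epidermis and guard cell markers, 4 fell and 5 were not called, 4 when adjusted over the list alone, with a median of −1.10. FDH, of cuticular wax synthesis, fell from 59.7 ± 9.55 to 14.5 ± 2.77 FPKM, PDF1 from 4.86 ± 0.0959 to 0.612 ± 0.1502, TGG1 from 203 ± 7.81 to 77.4 ± 1.06, and ATML1 from 13.1 ± 2.23 to 4.67 ± 0.415. The list had an adjusted p of 0.00243, and an adjusted p = 0.306 with an estimated correlation, so 4 lists were called and 0 held with an estimated correlation. The lists called numbered 9 without Mock replicate 2 and 7 without DC3000 replicate 2. Abscisic acid genes had 7 members that rose and 1 that fell among 28, with 9 and 1 when adjusted over the list alone (median 0.79, list adjusted p = 0.0691). NCED3, of abscisic acid synthesis, rose from 16.6 ± 1.17 to 71.6 ± 27.2 FPKM, ABI1 rose from 57.0 ± 15.2 to 250.1 ± 56.8, and RD22 fell from 67.3 ± 14.1 to 12.0 ± 4.38. NCED5 had 1 Mock and 74 DC3000 reads, a ratio of 36.4 (95% exact interval 6.34 to 1457). Of 10 senescence genes, 4 rose, 5 when adjusted over the list alone (median 0.75, list adjusted p = 0.0643). NAP rose from 15.2 ± 1.86 to 79.4 ± 34.9 FPKM, NAC092 from 16.5 ± 2.33 to 72.1 ± 10.1, NYC1 from 31.5 ± 8.14 to 75.0 ± 12.9 and PPH from 34.7 ± 3.39 to 68.3 ± 6.23.

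In the pattern-triggered immunity list, 2 of 27 members fell, FLS2 and WRKY22 (125 ± 0.755 to 64.2 ± 16.5 FPKM), and 25 were not called, with 0 when adjusted over the list alone. The median was −0.14 (list adjusted p = 0.0801) and turned to 0.21 with the scaling as deposited, where 4 members rose and 1 fell, against 3 falls with median-of-ratios factors. FRK1 stood at 14.2 ± 10.2 and 11.2 ± 2.07 FPKM (adjusted p = 0.87), and its sign turned with that scaling. Heat shock factors had 2 rises, HSFB2A (24.2 ± 0.428 to 55.6 ± 19.9 FPKM) and HSFB2B (9.89 ± 0.178 to 23.602 ± 0.934, overlapping AT4G11670 over 22.4% of its length). They had 2 falls, HSFA3 (14.7 ± 3.196 to 5.04 ± 1.24) and HSFA9 (134 ± 28.8 to 42.7 ± 12.3). HSFA9 overlaps the U3D small nucleolar RNA locus, so its fall may be one of reads of that locus. Small nucleolar and small nuclear RNA loci took 1.179% and 1.095% of tags in Mock and 0.589% and 0.764% in DC3000. Whether HSFA9 itself fell cannot be told from these reads. The heat shock factor list had a median of 0.31 and an adjusted p of 0.701, and 5 rises and 2 falls with the scaling as deposited. Large chaperones had 2 falls among 28, HSP90.5 (12.97 ± 1.74 to 6.47 ± 0.613 FPKM) and cpHsc70-1 (41.2 ± 2.17 to 22.6 ± 2.63), with a median of −0.06 (list adjusted p = 0.0801) that turned to 0.26 with the scaling as deposited, where 2 members rose and 0 fell. Small heat shock proteins had 1 fall among 16 and a median of −0.01 (list adjusted p = 0.436) that turned to 0.16, with 1 rise and 1 fall there. HSP17.8 stood at 14.2 ± 4.81 and 14.5 ± 4.76 FPKM and HSP17.6B at 18.9 ± 4.49 and 12.3 ± 5.78. Single members also rose in the unfolded protein response (ERDJ3A), phloem (SWEET12) and dividing cell (CDKB2-1) lists, with list adjusted p of 0.0801, 0.772 and 0.0801. Adjusted over the list alone, 0, 1 and 3 members rose, so ERDJ3A was not called there. The rises in these 3 lists numbered 7, 1 and 3 with the scaling as deposited and 1, 1 and 0 with median-of-ratios factors. Other heat-response genes (median 0.41, list adjusted p = 0.232), auxin response (0.22, 0.772), the circadian clock (0.31, 0.679) and root markers (0.00, 0.772) had 0 limma calls, though with the scaling as deposited 3 other heat-response genes and 3 auxin response genes rose. The clock list's median was positive while its test pointed down. Among the 12 root markers, 6 carry no fold because their reads were at or near 0, and the median without them was −0.05. In these lists ZAT10 stood at 465 ± 0.284 and 583 ± 24.8 FPKM, APX1 at 131 ± 27.4 and 107 ± 10.2, BZIP60 at 194 ± 24.7 and 284 ± 23.1, HSP90.7 at 35.0 ± 8.49 and 30.6 ± 7.18, IAA2 at 148 ± 3.06 and 301 ± 2.48 and PIF4 at 39.5 ± 2.85 and 68.8 ± 14.6. LNK2 stood at 166 ± 61.0 and 76.3 ± 5.60 FPKM, LHY at 13.4 ± 5.13 and 13.2 ± 4.75, SCR at 12.6 ± 5.05 and 9.68 ± 0.204, SUC2 at 37.2 ± 3.61 and 30.6 ± 4.28, SWEET11 at 12.6 ± 0.531 and 11.8 ± 3.80, KNOLLE at 4.55 ± 0.639 and 6.30 ± 1.87 and CDKB1-1 at 3.44 ± 1.76 and 7.37 ± 1.204. The signs of APX1, HSP90.7, LHY, SCR, SUC2 and SWEET11 turned with the scaling as deposited, and that of HSP17.8 with median-of-ratios scaling.

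The largest rises with a symbol, beside BSMT1 and WRKY38, were those of TPS02, a terpene synthase (0.234 ± 0.148 to 57.2 ± 19.6 FPKM, log2 change 5.52), TSA1 (2.91 ± 0.532 to 108 ± 26.3, log2 change 4.79), WRKY51 (1.64 ± 0.536 to 56.8 ± 1.77, log2 change 4.47) and AGL61 (0.858 ± 1.21 to 34.4 ± 6.89, log2 change 4.41). The largest falls were those of EXL3 (102 ± 26.48 to 8.48 ± 7.06 FPKM, log2 change −3.65), GER1 (1024 ± 23.496 to 83.5 ± 20.4, −3.62), FLA13 (149.8 ± 28.9 to 11.8 ± 4.65, −3.60), GASA6 (110 ± 9.84 to 9.16 ± 1.66, −3.46), XTH4, a cell wall xyloglucan enzyme (116 ± 7.97 to 18.24 ± 20.7, −3.22) and FLA9 (208 ± 59.9 to 25.9 ± 17.77, −3.11). GER1 lies wholly inside AT1G72600, so their reads cannot be separated.

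**Figure D2:**
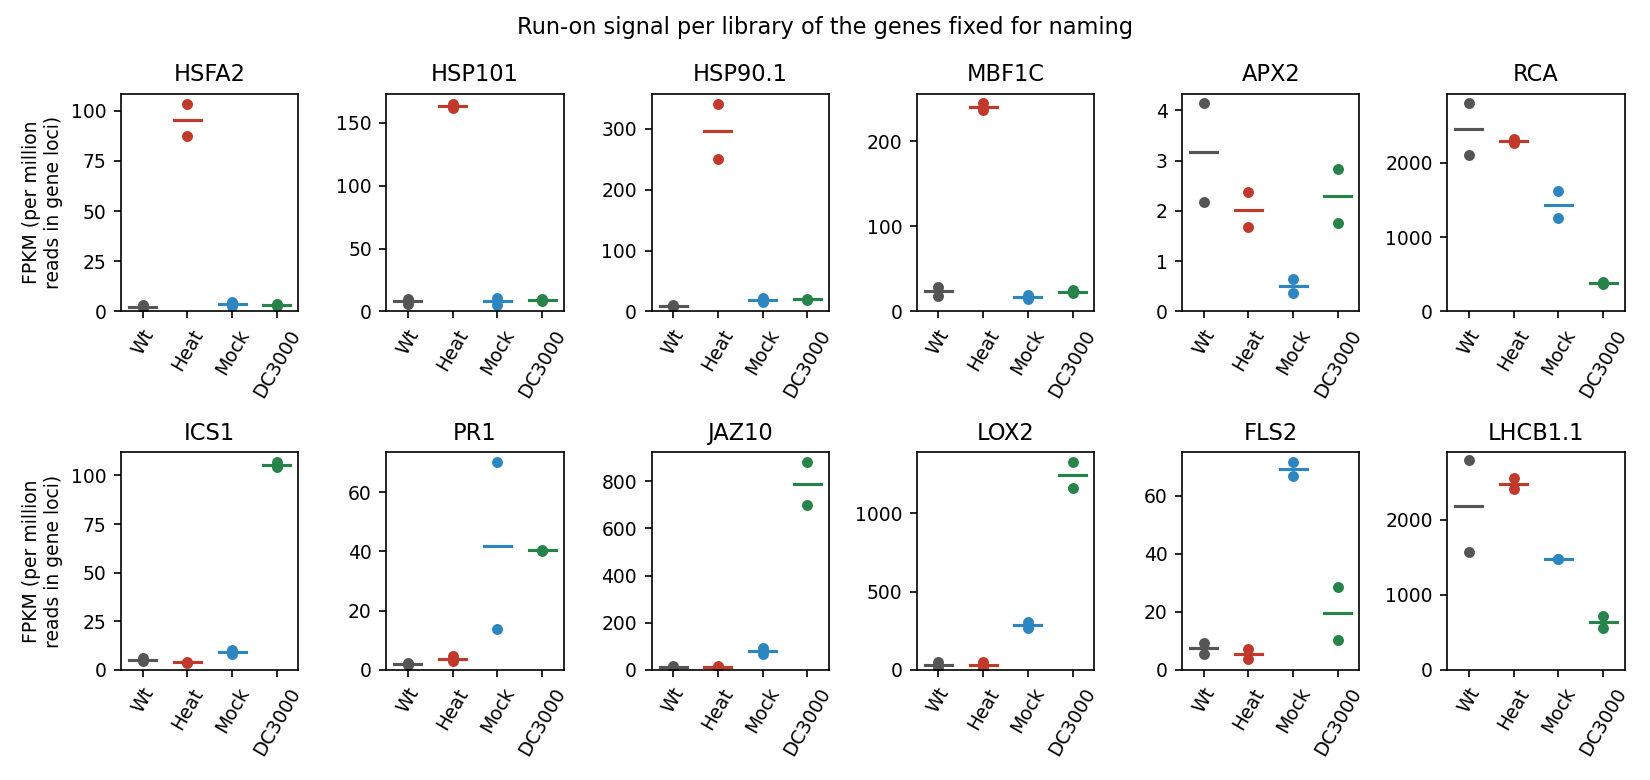
Points give FPKM scaled to reads in gene loci, 1 point per library, for 6 genes of the heat comparison (upper row) and 6 of the DC3000 comparison (lower row), and horizontal lines give group means of 2 libraries. HSFA2, HSP101, HSP90.1 and MBF1C were higher in both Heat libraries than in both Wt libraries, and ICS1 and JAZ10 were higher in both DC3000 libraries than in both Mock libraries.

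Of the rises and falls, 1905 and 1147 lay at loci averaging 2 CPM or more, and the unadjusted p was under 0.05 at 7126 loci. Fitted on the leaf libraries alone, limma called 2835 rises and 1304 falls. In simulated data for this comparison, under the same settings as for heat, 14 of 101 calls were false, all below 2 CPM. Of the simulated rises, 10% of 2-fold and 88% of 4-fold ones were recovered. The median of all genes was 0.18 here, 0.04 with median-of-ratios factors and 0.45 with the scaling as deposited, and changes were tested against 0, not against this median. Rises made up 64.3% of calls, against 53.2% and 88.2% under those scalings. In the salicylic acid, jasmonate, photosynthesis, abscisic acid and senescence lists, 16, 18, 23, 7 and 2 members were called with median-of-ratios factors and 25, 31, 36, 13 and 5 with the scaling as deposited. Calls of CBP60G, LHCB1.1, HSFB2A, NYC1 and PPH ended with median-of-ratios factors, and those of HSP90.5, cpHsc70-1, WRKY22 and ATML1 with the scaling as deposited. Rises and falls numbered 723 and 216 without Mock replicate 1, 583 and 280 without Mock replicate 2, 191 and 129 without DC3000 replicate 1, and 689 and 506 without DC3000 replicate 2. Of the 46 named genes called, the fits without a Mock replicate kept 20 and 28, and those without a DC3000 replicate, where TPS02 and NCED5 were not tested, kept 14 and 30 of 44. ICS1, JAZ10, BSMT1, CLH1, PBS3, WRKY38, TSA1, WRKY51, AGL61, GER1, FLA13, RD22 and PDF1 kept their calls without any 1 library, while XTH4 kept its call in 1 of 8 such fits, CBP60G and LHCB1.1 in 2, and FLS2, EXL3 and GASA6 in 4.

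**Figure D3:**
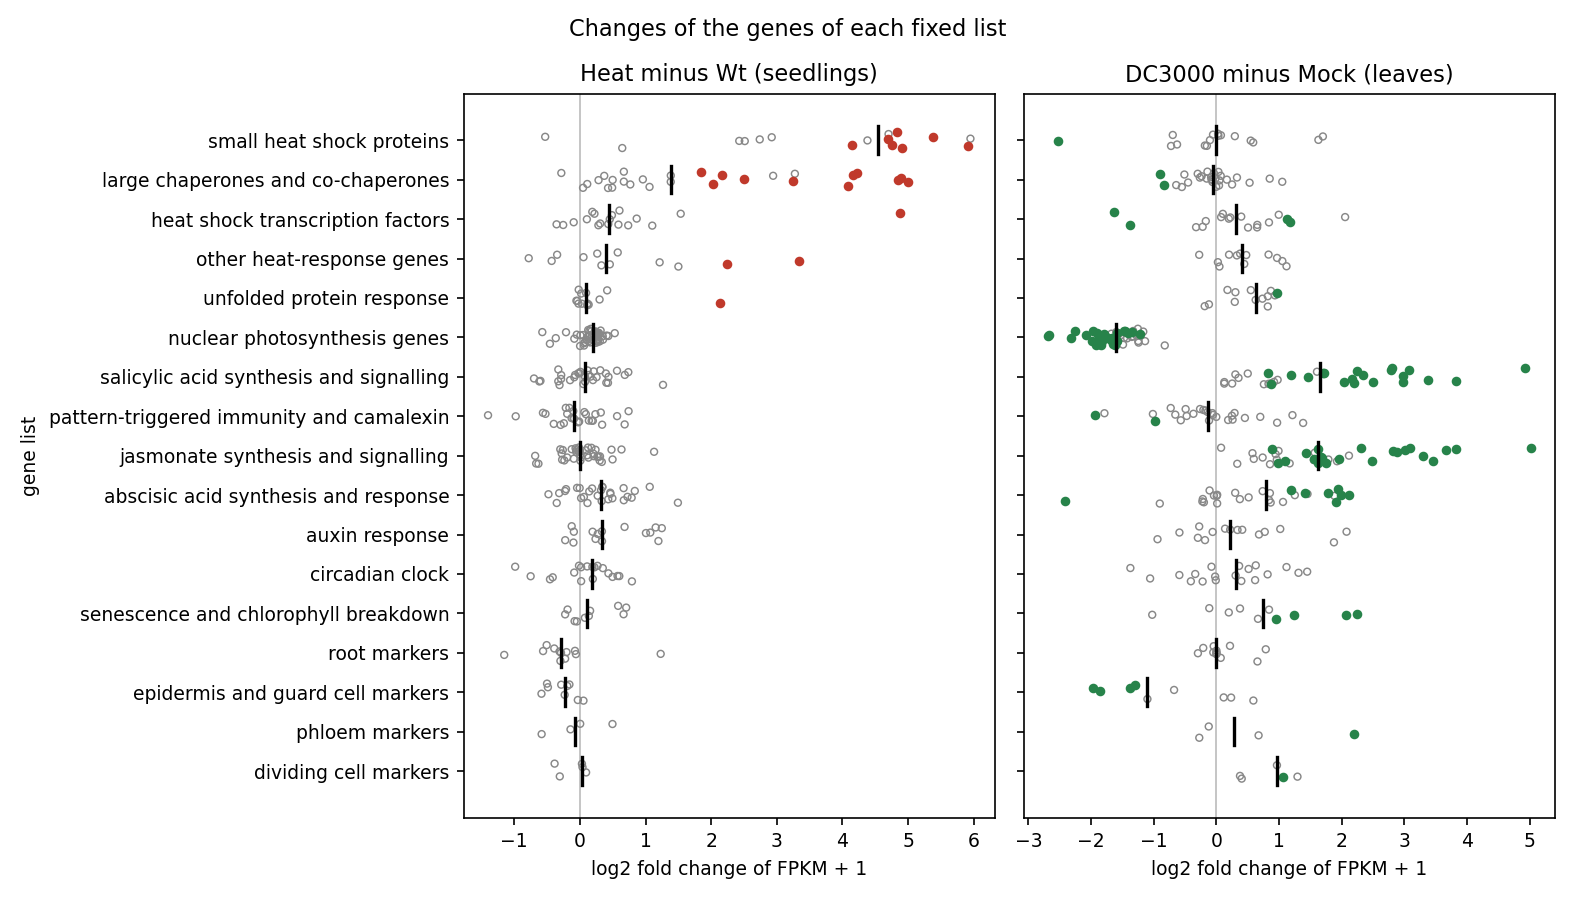
Each point is 1 gene of a fixed list, placed by its log2 fold change of FPKM + 1 for Heat minus Wt (left) and DC3000 minus Mock (right). Filled points passed an adjusted p of 0.05, and black lines give list medians, 4.54 for small heat shock proteins after heat and −1.61 for photosynthesis genes after DC3000.

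The third comparison set mock-infiltrated leaves against untreated seedlings as context. Age, organ, growth on soil and infiltration differed together here. Among the largest falls, PRP3, a root hair cell wall protein on the root marker list, had 299 Wt reads and 0 Mock reads, at least 119-fold lower, and EXT13, an extensin outside that list, had 267 and 0, at least 107-fold lower. Of 12 root markers, 9 fell and 3 were not called, 10 falling when adjusted over the list alone, with a fitted median of −2.10 and −3.00 with members of no Mock read at their bound, and an adjusted p = 0.224 with an estimated correlation. In all, 1516 loci rose and 2436 fell.

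The largest rises were those of NATA1 (0 Wt and 530 Mock reads, at least 148-fold higher), ELI3-2 (a read ratio of 468, 95% exact interval 129 to 3868), JRG21 (1.498 ± 0.843 to 117 ± 40.9 FPKM) and the transcription factor gene NAC019 (2.15 ± 1.102 to 112 ± 28.9). HRGP1 and DR4 fell from 903 to 1 read and from 335 to 1 read, control over treated ratios of 1081 (194 to 42741) and 401 (71.5 to 15886). All 8 of these genes stayed called without any 1 library. Salicylic acid genes had 14 rises among 32, 20 when adjusted over the list alone (median 0.98), pattern-triggered immunity 16 among 27, 19 over the list alone (median 1.21), and jasmonate 20 rises and 1 fall among 37, 27 and 2 over the list alone (median 1.51). Their list adjusted p were 2.01e-11, 5.74e-13 and 2.35e-15, and with an estimated correlation the adjusted p was 0.22, 0.224 and 0.22. Root and dividing cell markers (4 of 5 fell, median −1.37) had list adjusted p of 6.25e-07 and 0.011, and with an estimated correlation an adjusted p of 0.224 and 0.22. Small heat shock proteins had 3 rises among 16 (median 0.87), senescence genes 5 rises and 1 fall among 10 (1.06), epidermis markers 4 falls among 9 (−0.54) and abscisic acid genes 3 rises among 28 (0.43), with list adjusted p of 0.000785, 0.00163, 0.012 and 0.0193, and with an estimated correlation an adjusted p of 0.422, 0.22, 0.255 and 0.255. Large chaperones had 2 rises and 8 falls among 28 (median −0.47, list adjusted p = 0.0692), but 2 and 4 with median-of-ratios factors and 2 and 2 with the scaling as deposited. With that scaling the falls of root, epidermis and dividing cell markers numbered 6, 2 and 2, and the abscisic acid list had an adjusted p of 0.0525. Rises made up 38.4% of calls, against 48.9% with median-of-ratios factors and 67.2% with the scaling as deposited. Rises and falls numbered 760 and 1227 without Mock replicate 1 and 353 and 547 without Mock replicate 2, and falls numbered 1382 without Wt replicate 1.

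The fourth comparison tested whether the response to DC3000 differed from the response to heat. Organ, age, growth on soil and time after treatment (24 h and 0.5 h) also differed between these responses. The comparison cannot separate them from the kind of treatment. HSP17.8 had a difference of −5.36 ± 0.45 (SE) on the log2 scale (adjusted p = 0.0102). The differences of HSP17.6B, HSP23.6, HSP17.6A and HSP17.6II were −5.53, −5.53, −6.00 and −6.64. HSP23.6 and HSP17.6II had 1 read each in the Wt group, and HSP23.6 at most 5 in any leaf library, so these sizes are uncertain. HSP17.6A was not called after heat, and its difference ranged from −7.04 to −4.96 when leaving out each library. Among small heat shock proteins 7 of 16 were lower in the DC3000 response, 12 over the list alone, and among large chaperones 12 of 28, 21 over the list alone. With an estimated correlation the adjusted p was 0.228 and 0.0162. In the other direction stood TPS02 (5.52), BSMT1 (5.32), TSA1 (4.87), WRKY51 (4.68) and PBS3 (4.52). The value of TPS02 equals its DC3000 change alone. TPS02 passed the filter through the DC3000 libraries only, so its difference says nothing of an answer to heat. Salicylic acid genes had 8 of 32 higher in the DC3000 response, 15 over the list alone, and jasmonate genes 7 of 37, 21 over the list alone, with an adjusted p of 0.251 and 0.228 with an estimated correlation. In photosynthesis 3 of 48 were lower, 42 over the list alone, with an adjusted p of 0.262 with an estimated correlation. The salicylic acid, jasmonate and photosynthesis calls numbered 5, 3 and 0 with median-of-ratios factors and 15, 22 and 6 with the scaling as deposited. In all, 442 loci were higher and 177 lower. Higher calls made up 71.4%, against 67.8% with median-of-ratios factors and 92.1% with the scaling as deposited. Higher and lower calls numbered 152 and 57 without Wt replicate 1, 855 and 413 without Wt replicate 2, 69 and 15 without Heat replicate 1, and 71 and 13 without Heat replicate 2. They numbered 6 and 1 without Mock replicate 1, 75 and 14 without Mock replicate 2, 3 and 1 without DC3000 replicate 1, and 8 and 3 without DC3000 replicate 2. Of the 10 genes named here, 0 stayed called without Mock replicate 1 and 6 without Mock replicate 2, and of the 9 other than TPS02, which was not tested without a DC3000 replicate, 0 stayed called without DC3000 replicate 1 and 2 without DC3000 replicate 2.

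With limma 2 loci, ERDJ3A and TIN1, named after their values were seen, rose in both responses and 0 fell in both. Of these loci, ERDJ3A was not called after DC3000 when adjusted over its list alone. The counts of loci called in both moved with the model. No chance count is set beside them, since both responses use the same variance estimate per gene and their calls are not independent. Of the 12 loci that fell after heat, 11 of them below 2 CPM, 8 rose after DC3000. The tRNA locus AT1G28870 was called higher after heat and lower after DC3000 from 0 Wt, 3 Heat, 2 Mock and 0 DC3000 reads. The loci rising in both numbered 9 without Wt replicate 1, and 0 without either Heat, either Mock or either DC3000 replicate. Of the loci falling in both, 1 was called without DC3000 replicate 1.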

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

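The tests of ribosomal share, of flanks of uncalled genes, of clock genes and of loci that fell after heat were chosen after the result was seen, and those of genomic DNA and of transcription beside genes that rose were written down before their values were computed. Intergenic segments, outside the main measurement, held 21.8 ± 1.13 reads per 100 reads in gene loci in DC3000 and 12.5 ± 0.914 in Mock (n = 2), a ratio of 1.746.

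A lower ribosomal share alone would leave reads per gene-locus read alike, and the ratio of 1.746, with both DC3000 libraries above both Mock libraries, argues against it. Genomic DNA would add reads evenly, but 364 protein-coding loci with a Heat read and no Wt or Mock read gained 0.103 and 0.109 of the intergenic gain per kilobase in the 2 DC3000 libraries, and segments beyond 5000 bp from a feature had a ratio of 0.504. Transcription beside genes that rose may account for part: within 1000 bp their flanks gained 0.824 more on the log2 scale than flanks of uncalled genes. Whether such transcription is the whole cannot be told from flanks of other genes. Flanks of uncalled genes gained 0.996 and those of genes that fell gained 0.427. These flanks were counted even where they also lay beside a gene that rose, and uncalled genes can include undetected rises. By distance from the nearest feature, the DC3000 over Mock ratio was 1.884 within 500 bp and 1.897 from 500 to 1000 bp. It was 1.184 from 1000 to 2000 bp and 0.687 from 2000 to 5000 bp, so the gain lay near features. A biological change of transcription beyond gene ends stays open and was not tested.

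Clock genes differed between replicates in seedlings, with LHY at 240 and 25.8 FPKM in Wt and 150 and 9.91 in Heat. Lower depth of Wt replicate 2 does not account for it, since morning genes differed by 1.751 on the log2 scale in Heat, where replicate 2 was deeper. Collection at different times of day is a candidate explanation that stays open: morning genes exceeded evening genes by 0.945 in Wt and 1.338 in Heat, short in Wt of the 1 required. The same difference was 1.257 in Mock and 0.716 in DC3000. Evening genes themselves had a median of 1.041 in Wt and 0.412 in Heat, replicate 1 minus replicate 2. Both medians were thus higher in replicate 1 of the seedlings, but not every gene was. GI (−0.224 in Wt, −0.796 in Heat) and CHE (−1.211, −0.432) were lower there, and the other evening genes higher. PRR7, assigned to neither phase, was also lower (−0.907, −0.666). Among the higher evening genes, ELF4 had 9 and 1 reads in Wt and BOA 17 and 0. In leaves the evening median was −0.633 in Mock and −0.08 in DC3000. No biological explanation was tested.

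The 12 loci that fell after heat were 72 to 174 bp long, 7 of them transfer RNA genes, with 1 to 16 reads per Wt library and at most 2 per Heat library. Few reads per locus may account for these calls, as voom on recovered reads called 0 of them, and 11 lay below 2 CPM. No biological explanation was tested.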

How the results depend on the processing

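Median-of-ratios and deposited scaling, the 1.5-fold threshold, voom with and without the block, empirical Bayes without the robust option, and intergenic reads per gene-locus read were chosen after the results were seen. The replicate numbers come from titles and do not establish pairs. The file headers number the libraries otherwise, 1 and 3 in Wt and Heat and 2 and 3 in Mock and DC3000, so other replicates may exist, and the block joins libraries only within seedlings and within leaves, where both numberings agree. Deviations of same-numbered libraries correlated at 0.607 between Wt and Heat and at 0.234 between Mock and DC3000. Levels correlated at 0.957 and 0.961 between same-numbered Wt and Heat libraries, against 0.925 between the Wt and 0.955 between the Heat replicates. In leaves they correlated at 0.807 and 0.873 between same-numbered libraries, against 0.853 and 0.816 between differently numbered ones and 0.972 and 0.968 within Mock and DC3000. The fits of only the groups compared and those leaving out a library model no structure by replicate number. With the replicate number as a block, rises and falls numbered 33 and 14 for heat, 3540 and 1931 for DC3000, 2339 and 3985 for leaf against seedling and 1361 and 709 for the difference, with 6 rises in both responses. With voom and the block they numbered 99 and 50, 5108 and 3035, 2785 and 5019, and 2369 and 1519, with 25 rises and 22 falls in both. Fitting only the groups compared left 0 heat rises and 0 falls, 763 and 933 leaf calls, and 0 rises in both. The 1.5-fold threshold left 20 heat rises, 529 and 213 DC3000 calls, 437 and 614 leaf calls, 103 and 27 for the difference and 0 rises in both. The scaling as deposited gave 7 heat falls, 4258 and 567 DC3000 calls, 842 leaf falls, and 1242 and 107 for the difference. A mean of at least 2 CPM left 1 heat fall and 5 rises in both. A pseudocount of 0.1 gave 19 heat falls, 243 higher in the difference and 5 rises in both, and one of 5 gave 7 heat falls, 0 rises in both and 1 fall in both. Voom gave 0 heat falls, 1774 DC3000 falls, 415 lower in the difference and 4 rises in both. With an estimated correlation 1 heat list and 0 DC3000 lists were called. The intergenic ratio of DC3000 over Mock was 2.319 of tags and 1.746 per gene-locus read. Without the robust option the counts of loci called in each comparison and in both responses stayed within 1.5 times their values in the report.

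Leaving out each library in turn, where the lone sample is assumed to vary like the other groups, heat rises ranged from 5 to 34 and falls from 2 to 11. DC3000 rises ranged from 191 to 2823 and falls from 129 to 1445, leaf rises from 353 to 1365 and falls from 547 to 2557, and the difference from 3 to 855 higher and 1 to 413 lower. Rises in both ranged from 0 to 9, falls in both from 0 to 1, heat lists called from 6 to 11 and DC3000 lists from 4 to 9. With the scaling as deposited, the heat list medians that turned sign were salicylic acid synthesis and signalling −0.009, jasmonate synthesis and signalling −0.062, dividing cell markers −0.030. With the scaling as deposited, the heat changes that turned sign were CDKB1-1 −0.027. With median-of-ratios scaling, the heat list medians that turned sign were jasmonate synthesis and signalling −0.005. With voom, the heat changes that turned sign were LOX2 0.033, LNK2 0.002, CDKB1-1 −0.001. With the scaling as deposited, the DC3000 list medians that turned sign were small heat shock proteins 0.16, large chaperones and co-chaperones 0.26, pattern-triggered immunity and camalexin 0.21. With the scaling as deposited, the DC3000 changes that turned sign were FRK1 0.21, APX1 0.13, HSP90.7 0.21, LHY 0.33, SCR 0.067, SUC2 0.12, SWEET11 0.24. With median-of-ratios scaling, the DC3000 changes that turned sign were HSP17.8 −0.14. With voom, the DC3000 changes that turned sign were HSP17.8 −0.061. With voom with the block, the DC3000 changes that turned sign were HSP17.8 −0.063.

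Leaving out libraries, the heat list medians that turned sign ranged over nuclear photosynthesis genes −0.41 to 0.79, salicylic acid synthesis and signalling −0.031 to 0.23, pattern-triggered immunity and camalexin −0.32 to 0.20, jasmonate synthesis and signalling −0.16 to 0.22, circadian clock −0.44 to 0.74, senescence and chlorophyll breakdown −0.007 to 0.17, root markers −0.64 to 0.14, phloem markers −0.60 to 0.59, dividing cell markers −0.17 to 0.057. Leaving out libraries, the heat changes of uncalled genes that turned sign ranged over LHCB1.1 −0.17 to 0.66, RCA −0.29 to 0.12, HSFA9 −0.14 to 0.70, HSFA4A −0.41 to 0.22, BZIP60 −0.36 to 0.59, RBCS1A −0.32 to 0.22, WRKY33 −0.56 to 0.13, LOX2 −1.17 to 1.14, JAZ9 −0.71 to 0.23, CYP707A3 −0.56 to 0.47, IAA2 −0.12 to 0.66, LNK2 −0.57 to 0.54, LHY −2.88 to 0.91, SEN1 −0.12 to 1.45, WRKY6 −0.65 to 0.28, TGG1 −0.32 to 0.002, SWEET11 −1.48 to 0.32, CDKB1-1 −0.17 to 0.24. Leaving out libraries, the DC3000 list medians that turned sign ranged over small heat shock proteins −0.66 to 0.66, large chaperones and co-chaperones −0.29 to 0.009, pattern-triggered immunity and camalexin −0.35 to 0.033. Leaving out libraries, the DC3000 changes of uncalled genes that turned sign ranged over PR1 −0.78 to 1.48, FRK1 −0.88 to 0.60, HSP17.8 −0.30 to 0.35, HSP90.7 −0.43 to 0.056, LHY −0.39 to 0.35, SCR −0.68 to 0.093, SWEET11 −0.43 to 0.18. The cause of these changes was not tested. The planned count-model alternatives (other count tools and normalization factors, a legacy fit and a fold threshold) and the fit over all features that name a gene were not run as written, and the one for binned files does not apply. Loci below 2 CPM hold few reads, and false calls in simulated data lay mostly there.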

Other observations

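The features and genes in this part, and the tests on them, were chosen after the results were seen. Outside the fixed lists, 7 loci at 2 CPM or more rose after heat, among them TIN1 (log2 change 2.69) and PDX1.2 (2.51). Reads within 1000 bp of the genes that rose after heat had a median log2 change of 0.595, positive beside 20 of 26 genes with enough flanking reads and higher in both Heat than in both Wt libraries beside 10, against 0.009 beside 17098 uncalled genes, positive beside 8676 and higher in both beside 2471.

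Of 9164 features of a non-coding RNA catalogue, 7062 overlapped no gene locus and 3390 of those were tested with limma. After heat 0 rose and 0 fell, with 220 at an unadjusted p under 0.05. After DC3000, 73 rose, 42 of them at 2 CPM or more, and 20 fell, all at 2 CPM or more, with 847 at an unadjusted p under 0.05. The whole catalogue held 5.36 reads per 100 reads in gene loci in DC3000 and 7.07 in Mock. Intergenic segments within 500 bp of a feature had a DC3000 over Mock ratio of 1.884. Whether calls near a gene reflect reads of that gene was not tested. At1NC073270 (chromosome 1 from 19518512 to 19518762 in TAIR10), 101 bp from AT1G52400, had 0 reads in both Mock libraries and 42.6 ± 17.0 FPKM in DC3000. LincRNA_1477 (chromosome 4 from 6880685 to 6881091), 2460 bp from the nearest gene locus, rose from 1.79 ± 1.13 to 53.0 ± 17.2 FPKM. NAT-lncRNA_932 (chromosome 4 from 7758205 to 7758487), 123 bp from AT4G13340, fell from 423 ± 82.4 to 87.6 ± 36.0 FPKM. LincRNA_1654 (chromosome 5 from 11188310 to 11188484), 2059 bp from AT5G29560, fell from 1063 ± 97.8 to 306 ± 80.6. Ribosomal DNA was also lower in DC3000, at 17.9 ± 6.33 reads per 100 reads in gene loci against 64.1 ± 8.29 in Mock. Whether these falls share a cause was not tested.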
